A study of Oryza sativa with 64 samples.

How the data were processed

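Expression and small RNA tables of rice lines edited at the DNA methyltransferase genes OsCMT2, OsCMT3a and OsDRM2 were re-analysed from the files as deposited. No reads were aligned again. The tables covered 30 mRNA libraries, 3 from each of 10 groups, and 10 small RNA libraries. The groups were WT set 1, WT set 2, the 3 single mutants, the 3 double mutants, and the triple mutant as set 1 and set 2. Per the labels, the plants were of the T1 generation, the WT plants came from callus, and leaves were taken at 70 days. Groups were taken from the labels alone, which do not say which WT set belongs to which mutant. The bisulfite libraries of the series were not used here.

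Per the submitters' processing notes, cutadapt 1.18, HISAT2 2.1.0, StringTie 1.3.3b and Bowtie 1.2.2 were used for the series, without their order or settings, and no genome build is named. The mRNA tables hold 55801 loci with MSU style names. Per the file headers, each deposited mRNA table gives the read coverage of a locus (the mean per base, not scaled for library size), its FPKM value and its TPM value. The authors scaled FPKM and TPM for library size and locus length, and the deposited TPM values of a library sum to the same total in every library. TPM values were used for the tests, and the FPKM and coverage columns only to check the units and to estimate depth. Such values are not counts of reads, so no model of counts was fitted. The small RNA files as deposited list chromosome, strand, position and length of alignments of 18 to 28 nt. Each alignment occurs once in a file, without the number of reads behind it. Shares and bin values are therefore shares of distinct alignments, which level off as depth grows.

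Depth, taken as the median ratio of coverage to FPKM over loci above 1 FPKM, was 5.18 to 6.98 gigabases per mRNA library, and there were 661311 to 2366085 distinct alignments per small RNA library. The 10 loci with the highest values took 8.25 to 16.0% of the TPM of a library. Libraries of the same group had correlations of 0.986 to 0.994 on the log2 scale. A share of a length class in 1 small RNA library has a 95% Wilson interval, which covers counting error only.

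A locus was tested when it reached 1 TPM in at least 3 of the 30 libraries, which left 22787. Values were transformed to log2(TPM + 1), a scale that understates the change of low loci. The 10 groups were fitted together with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3, so that they share one estimate of the spread. For a mutant, the larger of the p-values against WT set 1 and WT set 2 was adjusted by Benjamini-Hochberg over all tested loci. A locus was called when this adjusted p was under 0.05 and both log2 changes had the same sign and a size of at least 1. The same rule was used for the interaction of cmt2 and cmt3a, the double mutant minus both single mutants plus WT, with each WT set in turn, and for both triple mutant sets together, with 4 contrasts. Direct comparisons of groups used 1 contrast with the same thresholds. Unless another test is named, an adjusted p in the report comes from limma with Benjamini-Hochberg adjustment.

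The effect of losing each gene whatever the other genotypes was estimated on the 10 group means with an additive model of the 3 losses, 5 groups with a loss against 5 without it. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 120 tests, 15 lists in 8 mutants. The lists were circadian clock, defence, demethylation and remodelling, diterpenoid phytoalexin, DNA methyltransferase, flowering, heat shock, hormone and architecture, meristem markers, panicle markers, photosynthesis, root markers, seed markers, senescence and small RNA pathway genes. They were written before the data were examined, as were the tests, the thresholds and most of the alternatives below. Members called were counted both over all tested loci and after adjustment over the list alone.

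No table here pairs the locus names with gene names. List members were therefore given their locus by hand, and the RefSeq gene table (assembly ASM3414082v1) served only to check names. Of 147 members, 87 names stood on the same chromosome in the RefSeq table within 5 Mb of the expected place, 55 names, OsCMT2 among them, were not in that table, and 5 stood elsewhere and were left out, so that 142 were used. The report names the 3 edited genes, up to 4 members of each list per comparison (called ones first, by size, then the largest others), and at most 2 other loci that rose and 2 that fell. OsLHY in the triple mutant and LOC_Os04g36580 lie outside that rule and were chosen after their values were seen.

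Shares of 21, 22 and 24 nt alignments were compared between the 5 libraries with a gene mutated and the 5 with it intact by a two-sided exact permutation test, whose smallest p is 0.00794, with Benjamini-Hochberg adjustment over 9 tests. The same test was used for 4 places in the genome (12 tests), for alignments in and within 2 kb of the called loci (60 tests) and for the organelle chromosomes (6 tests), which were all chosen after the data were seen. The 24 nt alignments were also counted in bins of 10 kb on the 12 nuclear chromosomes. The 29777 of 37117 bins with at least 10 alignments in at least 3 libraries were tested with limma on log2 of the CPM plus 1, where CPM was computed here from the total of the library, with the additive model and the same thresholds.

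Overlaps of calls between lines that share WT libraries were set beside independent draws and 20 simulations of unchanged groups. Rescaling used size factors from medians of ratios over loci at 1 TPM or more in every library. The length trend was removed per library with a local regression of the deviation from the mean on log2 of the locus length, taken from the deposited start and end. Both the calls and the share of higher loci were computed again under these and other alternatives, which were another pseudocount (0.1), no filter, no minimum change, other uses of the WT sets, only the groups compared, a replicate block, an estimated correlation for lists, and each library or group left out. For the small RNA data they were TMM scaling, a stricter filter, lengths of 20 to 25 nt only and each library left out. Removal of the length trend, fits without the triple mutant or without the cmt2 and cmt3a lines, and thinning of the small RNA libraries to the smallest were added after seeing the data. The closing section gives their effect.

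The group comparisons, models of gene loss and bins were tested on simulated data with 100 changed features per size, built on the means of the real libraries and their spread. At changes of 1.5 on the log2 scale, 95 to 100% of changed loci were recovered in the 16 group comparisons and 50 to 60% in the 3 models of gene loss, and at changes of 3, 99 to 100% and 87 to 93%. False calls numbered 0 to 3 and 6 to 13. Gene loss was simulated with independent groups, which real ones need not be. The 2 WT sets differed at 567 loci, so both ranges may be too low. For the bins 69 and 97% were recovered by DRM2 loss, 71 and 97% by CMT2 loss and 64 and 98% by CMT3a loss, with 6, 6 and 3 false calls, and for the lists the 1 changed list was called with 0 false calls among 120 tests. In 100 simulations each, the exact permutation test recovered 100% of shifts of 10 SD when every measure shifted with 1 gene. When 1 measure shifted alone it recovered 4% in 9 tests, 6% in 12, 0% in 60 and 100% in 6, since 1 such p alone adjusts to 0.0714, 0.0952, 0.476 and 0.0476. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and figures.

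Levels of single microRNAs and the share of loci without a reference gene were planned but not analysed here, since the small RNA files hold no sequences or read numbers and no reference of the same build is at hand.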

Results

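Rice plants edited at the DNA methyltransferase genes OsCMT2, OsCMT3a and OsDRM2, singly and in every combination, were compared with wild type (WT) plants regenerated from callus, all of the T1 generation. The mRNA data held 30 libraries from mature leaves of 70-day-old plants, in 10 groups of 3. These groups were WT set 1, WT set 2, cmt2, cmt3a, drm2, cmt2/cmt3a, cmt2/drm2, cmt3a/drm2 and the triple mutant cmt2/cmt3a/drm2 as set 1 and set 2. The small RNA data held 10 libraries, with 1 library for each of 6 mutants and 2 each for WT and the triple mutant. Each mRNA library covered 5.18 to 6.98 gigabases, and each small RNA library listed 661311 to 2366085 distinct alignments. Of 55801 annotated loci, 22787 reached 1 TPM in at least 3 libraries and were tested. The labels do not say whether the replicates were separate plants, so each p-value measures the spread between libraries. Levels are mean TPM ± SD of 3 libraries (n = 3) and log2 changes are on log2(TPM + 1), given with their SE. The genome build is not given, the locus names follow the MSU style, and coordinates are those of the deposited tables.

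The first question was what became of the edited genes' own transcripts. OsDRM2 was not lowered in the lines edited in it, at 27.0 ± 0.985 TPM in drm2, 20.6 ± 2.45 and 24.2 ± 1.06 TPM in triple mutant sets 1 and 2, and 18.6 ± 0.461 and 21.9 ± 0.801 TPM in WT sets 1 and 2 (SD, n = 3). OsCMT2 stood at 3.91 ± 2.17 and 4.24 ± 1.68 TPM in the WT sets and at 2.18 ± 0.738 TPM in cmt2 (log2 changes -0.54 ± 0.33 and -0.69 ± 0.33, adjusted p = 0.198). In both triple mutant sets OsCMT2 rose, to 12.3 ± 2.52 TPM (adjusted p = 0.000683) and 10.6 ± 2.70 TPM (adjusted p = 0.00342). OsCMT2 held 8.80 ± 1.28 TPM in drm2, 5.60 ± 1.81 TPM in cmt3a/drm2 and 3.94 ± 2.96 TPM in cmt2/drm2, none of them called. Without WT set 2 replicate 1 or replicate 2 the drm2 value was called higher (smaller log2 change 1.10). OsCMT3a did not reach the level needed for a test, with 0.0167 ± 0.0290 TPM in WT set 1 and at most 0.0980 ± 0.127 TPM in any group. The OsCMT2 call in triple mutant set 2 was lost without WT set 1 replicate 2 (smaller log2 change 0.93), without WT set 2 replicate 3 (0.87) or with the length trend removed (0.93). Without cmt2/drm2 replicate 1 the OsCMT2 change in cmt2/drm2, which was not called, turned from negative to 0.10. An edit need not lower a transcript, so these levels do not check the genotypes.

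The 2 WT sets were compared to see how far libraries of the same genotype differed. Of 11 defence genes 3 were called higher in WT set 2 than in set 1 and none lower, all 3 of the pathogenesis-related class 10. RSOsPR10 rose from 7.90 ± 1.54 to 22.4 ± 2.42 TPM, OsPR10b from 7.71 ± 2.34 to 21.4 ± 2.80 TPM and PBZ1 from 81.0 ± 31.4 to 192 ± 27.9 TPM (SD, n = 3), while JIOsPR10 of the same class was not called (-0.17 ± 0.16, adjusted p = 0.478). SGR, which takes part in chlorophyll breakdown, rose from 1.97 ± 0.126 to 8.15 ± 0.925 TPM (adjusted p = 7.72e-10) and OsNAC2 from 1.75 ± 0.243 to 4.75 ± 0.369 TPM. The largest differences were at LOC_Os12g37415, with 33.0 ± 56.2 and 223 ± 47.3 TPM in sets 1 and 2, LOC_Os02g53240, with 1.76 ± 0.817 and 72.1 ± 12.0 TPM, LOC_Os04g08630, with 41.0 ± 3.90 TPM and listed at 0 in set 2, and LOC_Os07g05840, with 49.6 ± 5.04 and 0.455 ± 0.254 TPM. In total 567 loci differed, 480 of them higher in set 2, with the median of all tested loci shifted by 0.10. The calls of PBZ1 (log2 change 0.95 without WT set 1 replicate 2) and OsNAC2 (0.99 without WT set 1 replicate 3, 0.98 after rescaling, 0.88 with the length trend removed) were lost in those settings, and those of LOC_Os12g37415 and PBZ1 when only both WT sets were fitted. By the rule set beforehand, a change in a mutant was called only against both WT sets.

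**Figure D1:**
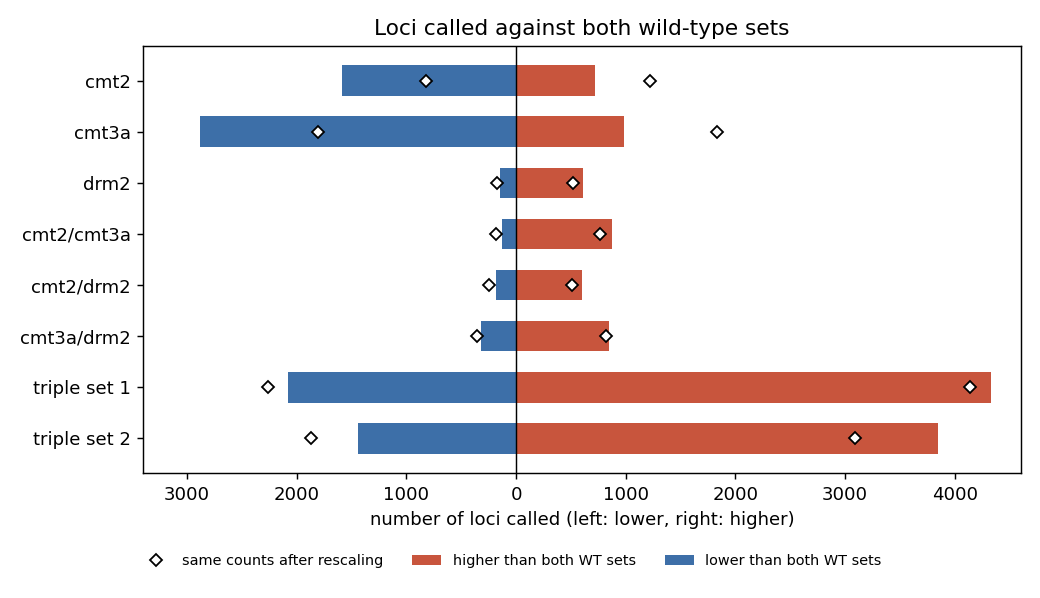
Number of loci called higher (right, red) and lower (left, blue) in each mutant than in both WT sets, with white diamonds for the counts after rescaling by median-of-ratios size factors. In cmt2 and cmt3a the lower calls outnumber the higher ones in the deposited TPM (1587 against 720 and 2882 against 988) but not after rescaling (819 against 1221 and 1803 against 1833).

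Loss of DRM2 alone was compared with WT to ask which leaf transcripts depend on this methyltransferase. Several defence genes rose in drm2, among them the chitinase gene Cht1, from 1.72 ± 0.123 and 3.08 ± 0.441 TPM in WT sets 1 and 2 to 13.1 ± 2.08 TPM (SD, n = 3, adjusted p = 9e-12). The transcription factor gene OsWRKY45 rose from 4.78 ± 0.42 and 7.34 ± 0.220 TPM to 16.6 ± 2.24 TPM. OsWRKY62 rose from 0.0367 ± 0.0636 and 0.0905 ± 0.109 TPM to 1.47 ± 0.266 TPM, and JIOsPR10 from 0.228 ± 0.199 and 0.0875 ± 0.0890 TPM to 1.82 ± 0.719 TPM. Of the 11 defence genes 5 rose and none fell, but the list as a whole was not called (adjusted p = 0.474). The silicon transporter gene Lsi1, a root marker, rose from 4.24 ± 1.2 and 4.72 ± 0.555 TPM to 12.2 ± 1.12 TPM. The floral organ gene OsMADS58 rose to 1.70 ± 0.837 TPM, against 0.0232 ± 0.0402 TPM in WT set 2 and 0 in each library of WT set 1. SD1, which encodes a gibberellin 20-oxidase, fell from 28.1 ± 5.71 and 31.6 ± 1.70 TPM to 13.1 ± 1.36 TPM.

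The largest changes in drm2 were at loci without a name here. LOC_Os01g45914 (chromosome 1, 26087572 to 26088335) rose from 1.26 ± 0.280 and 2.51 ± 1.09 TPM to 1495 ± 73.9 TPM (SD, n = 3, adjusted p = 7.2e-24). LOC_Os10g11889 (chromosome 10, 6597053 to 6599560) was listed at 0 in all 6 WT libraries and at 108 ± 4.01 TPM in drm2. LOC_Os11g41710 (chromosome 11, 25040876 to 25042999) fell from 28.2 ± 5.38 and 49.5 ± 3.92 TPM to 0.711 ± 0.0243 TPM. LOC_Os11g06980 (chromosome 11, 3463899 to 3468002) fell from 38.8 ± 34.3 and 83.3 ± 13.5 TPM to 0.269 ± 0.0555 TPM. In total 611 loci rose and 148 fell in drm2, where the median of all tested loci shifted by 0.11 on the log2 scale. The SD1 call was lost without WT set 1 replicate 2 (log2 change -0.88), without drm2 replicate 1 (-0.99) or without drm2 replicate 3 (-0.99), and that of JIOsPR10 without drm2 replicate 3 (0.99). With the length trend removed, OsWRKY45, OsWRKY62 and JIOsPR10 came to log2 changes of 0.998, 0.99 and 0.92, just short of the minimum.

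The cmt2 and cmt3a lines were compared with WT for the same question about the chromomethylases. In both lines the transcript of OsRCA, the Rubisco activase, fell, from 15456 ± 902 and 11767 ± 738 TPM in WT sets 1 and 2 to 4487 ± 275 TPM in cmt2 and 3148 ± 111 TPM in cmt3a (SD, n = 3, adjusted p = 1.55e-16 and 1.57e-19). The clock gene OsGI fell from 603 ± 68.8 and 597 ± 76.2 TPM to 234 ± 28.7 and 159 ± 7.18 TPM. SLR1, the DELLA repressor of gibberellin responses, fell from 97.1 ± 6.31 and 82.7 ± 10.0 TPM to 34.4 ± 3.67 and 17.3 ± 1.43 TPM. SD1 fell to 11.1 ± 1.31 and 5.42 ± 1.69 TPM. OsGA20ox1, another gibberellin 20-oxidase gene, rose from 4.94 ± 0.289 and 7.35 ± 0.531 TPM to 19.2 ± 2.55 and 22.0 ± 2.63 TPM. The flowering repressor gene DTH8 rose from 1.63 ± 0.0220 and 3.10 ± 1.02 TPM to 7.75 ± 0.967 TPM in cmt2 and 8.65 ± 0.514 TPM in cmt3a.

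Of 5 demethylation and remodelling genes 2 fell in each line, and of 12 small RNA pathway genes 1 fell in cmt2 and 2 in cmt3a, but neither list was called (adjusted p = 0.312 and 0.0799 in cmt2, and 0.314 and 0.138 in cmt3a). The DNA demethylase genes OsROS1a (34.4 ± 1.42 and 29.9 ± 9.00 TPM in WT sets 1 and 2) and OsROS1d (12.4 ± 0.594 and 10.6 ± 3.44 TPM) fell to 13.8 ± 3.45 and 4.75 ± 1.66 TPM in cmt2 and to 9.52 ± 1.15 and 3.86 ± 0.314 TPM in cmt3a (SD, n = 3). The argonaute gene OsAGO4b fell from 33.8 ± 1.45 and 32.2 ± 5.50 TPM to 14.9 ± 2.62 and 13.6 ± 1.45 TPM. OsNRPD1a, a subunit gene of RNA polymerase IV, fell in cmt3a from 8.20 ± 1.11 and 8.95 ± 1.72 TPM to 2.71 ± 0.411 TPM. The chaperone gene HSP70 fell from 222 ± 1.79 and 163 ± 25.1 TPM to 74.3 ± 6.53 and 76.7 ± 1.99 TPM. PAO, of chlorophyll breakdown, fell from 58.7 ± 4.57 and 50.9 ± 4.46 TPM to 20.7 ± 1.52 and 18.3 ± 2.61 TPM. The starch synthase gene Wx, a seed marker, fell from 4.23 ± 0.398 and 5.44 ± 0.584 TPM to 1.41 ± 0.201 and 1.01 ± 0.211 TPM. After rescaling, the changes of OsROS1a (-0.74), OsROS1d (-0.74), OsAGO4b (-0.76), HSP70 (-0.80), PAO (-0.95) and SLR1 (-0.93) in cmt2 and of OsROS1d (-0.93), OsAGO4b (-0.86) and HSP70 (-0.73) in cmt3a fell short of the minimum of 1 on the log2 scale. The cmt2 changes of OsROS1a, OsROS1d and OsAGO4b came to -0.83, -0.74 and -0.92 without cmt2 replicate 1. They came to -0.91, -0.89 and -0.98 without WT set 2 replicate 2 and to -0.89, -0.85 and -0.99 without WT set 2 replicate 3. The cmt3a change of HSP70 came to -0.99 without WT set 2 replicate 3.

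Some genes were called in only one of these lines, a difference that was not itself tested. In cmt2 JIOsPR10 rose to 1.90 ± 0.612 TPM and OsWRKY76 from 0.174 ± 0.259 and 0.251 ± 0.266 TPM in WT sets 1 and 2 to 1.70 ± 0.161 TPM (SD, n = 3). In cmt3a OsWRKY45 rose to 16.2 ± 1.27 TPM, while D14, the strigolactone receptor gene, fell from 484 ± 39.8 and 392 ± 19.8 TPM to 147 ± 4.85 TPM. Lower in cmt3a were also the clock gene OsLHY, from 285 ± 9.51 and 246 ± 55.3 TPM to 116 ± 6.39 TPM, and OsNPR1, from 6.82 ± 0.787 and 6.64 ± 1.10 TPM to 2.62 ± 0.376 TPM. OsPR1b fell from 5.21 ± 5.34 and 3.73 ± 0.905 TPM to 0.955 ± 0.278 TPM. The senescence regulator gene OsNAP fell from 13.1 ± 3.49 and 7.12 ± 1.11 TPM to 1.85 ± 0.590 TPM. The diterpene cyclase gene OsCPS4 fell from 2.51 ± 0.236 and 3.31 ± 0.912 TPM to 0.461 ± 0.0847 TPM, and the meristem gene FON1 from 7.43 ± 0.543 and 7.42 ± 0.912 TPM to 1.67 ± 0.209 TPM. Calls were lost for OsWRKY76 without WT set 2 replicate 1 (log2 change 0.98), OsWRKY45 without cmt3a replicate 2 (0.99), OsPR1b without WT set 1 replicate 2 (-0.68), and OsLHY without WT set 2 replicate 2 (-0.97) or replicate 3 (-0.94) and after rescaling (-0.72). The call of OsNPR1 was lost without WT set 2 replicate 3 (-0.96) or cmt3a replicate 3 (-0.99) and after rescaling (-0.81). OsPR1b was also lost when only cmt3a and the WT sets were fitted.

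The largest change in cmt2 was at LOC_Os11g32650 (chromosome 11, 19277557 to 19281016), which rose from 0.170 ± 0.0485 and 0.282 ± 0.00185 TPM in WT sets 1 and 2 to 67.5 ± 2.04 TPM (SD, n = 3, adjusted p = 3.2e-26). LOC_Os10g24004 rose there from 0.177 ± 0.0833 and 0.0864 ± 0.0675 TPM to 59.6 ± 8.78 TPM. LOC_Os10g05250 fell from 26.3 ± 5.43 and 27.4 ± 2.95 TPM to 1.05 ± 0.15 TPM. In cmt3a LOC_Os11g01310 rose from 0.780 ± 0.609 and 0.773 ± 0.313 TPM to 106 ± 4.89 TPM. LOC_Os02g22250 rose there to 52.0 ± 0.155 TPM, against 0.0238 ± 0.0411 TPM in WT set 2 and 0 in each library of WT set 1. LOC_Os07g48020 fell in cmt3a from 36.3 ± 11.4 and 20.7 ± 1.87 TPM to 0.122 ± 0.111 TPM. LOC_Os01g22249 (chromosome 1, 12509592 to 12519255) fell in both, from 29.3 ± 7.32 and 25.0 ± 1.17 TPM to 1.15 ± 0.147 TPM in cmt2 and 0.369 ± 0.0669 TPM in cmt3a.

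In total 2307 loci were called in cmt2, of which 720 rose and 1587 fell, and 3870 in cmt3a, of which 988 rose and 2882 fell. The median of all tested loci shifted by -0.13 in cmt2 and -0.14 in cmt3a on the log2 scale, and after rescaling the split was 1221 higher and 819 lower in cmt2 and 1833 and 1803 in cmt3a. Both lines shared 492 loci that rose and 1514 that fell, against 31.2 and 201 for independent draws and 0 in 20 simulations of unchanged groups with a shared WT, which leave out real changes and so do not show what the shared WT adds. With cmt2 set against WT set 1 alone and cmt3a against WT set 2 alone they shared 688 and 2030, and the other way round 606 and 1727. The libraries of both lines stood apart on the second principal component (20.8% of the variance), and longer loci were lower in them, by a median of -0.40 in cmt2 and -0.44 in cmt3a for the class of the longest loci. With that length trend removed, the splits were 1021 higher and 743 lower in cmt2 and 1553 and 1695 in cmt3a, though both corrections centre each library, which itself moves the split. The clock list was called lower in cmt2 (adjusted p = 0.0414, 1 of 10 genes called), but not with an estimated correlation (adjusted p = 0.62 with an estimated correlation), after rescaling, with the length trend removed or with a pseudocount of 0.1.

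Removal of the length trend also ended the following calls of named genes. In cmt2 these were OsGI (log2 change -0.79), OsROS1a (-0.42), OsROS1d (-0.42), OsAGO4b (-0.56), HSP70 (-0.81) and Wx (-0.87). In cmt3a these were OsLHY (-0.51), OsROS1a (-0.82), OsROS1d (-0.55), OsAGO4b (-0.63), OsNRPD1a (-0.88), OsNPR1 (-0.73), HSP70 (-0.74) and OsCPS4 (-0.70).

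The cmt2/cmt3a line was compared with WT and with each chromomethylase line to ask what joint loss does. Against WT, 4 of 11 defence genes rose and none fell, but the list was not called (adjusted p = 0.0611, and adjusted p = 0.196 with an estimated correlation). OsWRKY45 rose from 4.78 ± 0.42 and 7.34 ± 0.220 TPM to 39.0 ± 1.75 TPM (SD, n = 3, adjusted p = 1.11e-16). OsWRKY76 rose to 3.04 ± 0.218 TPM, OsWRKY62 to 1.70 ± 0.0554 TPM and JIOsPR10 to 1.54 ± 0.197 TPM. The floral identity gene OsMADS14 rose to 6.93 ± 0.690 TPM, against 0.0321 ± 0.0293 TPM in WT set 2 and 0 in each library of WT set 1. DTH8 rose to 7.88 ± 0.187 TPM and OsGA20ox1 to 19.3 ± 1.12 TPM, and SD1 fell to 13.2 ± 0.994 TPM. The photosynthesis list was called lower (adjusted p = 0.000709) at a median of -0.39 on the log2 scale with no single gene of 12 called, but not with an estimated correlation (adjusted p = 0.332 with an estimated correlation). LOC_Os08g08130 rose to 53.1 ± 3.17 TPM, against 0.0165 ± 0.0285 TPM in WT set 2 and 0 in each library of WT set 1. LOC_Os11g01310 rose to 89.9 ± 4.87 TPM. LOC_Os08g13440 fell from 480 ± 134 and 444 ± 46.7 TPM to 17 ± 2.81 TPM and LOC_Os01g22249 to 0.367 ± 0.221 TPM. In total 875 loci rose and 132 fell, with a shift of the median of 0.13. The SD1 call was lost without WT set 1 replicate 2 (log2 change -0.87) or cmt2/cmt3a replicate 1 (-0.96). The call of JIOsPR10 was lost without WT set 1 replicate 1 (0.92) or cmt2/cmt3a replicate 2 (0.996), after rescaling (0.98) and with the length trend removed (0.71).

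Several genes lowered in cmt2 and cmt3a stood closer to WT in cmt2/cmt3a. The interaction of both losses was tested, which asks whether the double mutant departs from the sum of both single changes. It does not test a return to WT, since a double mutant at the level of 1 single mutant can also give an interaction. SLR1 held 70.0 ± 1.93 TPM in cmt2/cmt3a, against 34.4 ± 3.67 TPM in cmt2 and 17.3 ± 1.43 TPM in cmt3a (SD, n = 3, interaction 3.44 ± 0.12 and 3.20 ± 0.12 with WT sets 1 and 2, adjusted p = 1.23e-17). The interaction of SD1 was called too, although SD1 was also called lower than WT in cmt2/cmt3a. OsGI held 404 ± 21.6 TPM, OsROS1a 26.5 ± 2.71 TPM, OsAGO4b 29.3 ± 1.39 TPM, OsNRPD1a 6.03 ± 0.847 TPM and OsRCA 6448 ± 168 TPM, and the interaction of each was called. The opposite held for the light-harvesting gene LHCB4, with 8005 ± 455 TPM in cmt2, 6996 ± 130 TPM in cmt3a and 4399 ± 140 TPM in cmt2/cmt3a, and for the Rubisco small subunit gene OsRBCS3, with 17125 ± 798, 19192 ± 449 and 11829 ± 66.3 TPM. OsMADS14 stood at 0.0755 ± 0.126 TPM in cmt2 and 0.189 ± 0.220 TPM in cmt3a, and its interaction was positive. LOC_Os10g05250 held 8.52 ± 0.541 TPM in cmt3a and 58.7 ± 4.09 TPM in cmt2/cmt3a. LOC_Os10g09300 held 3.14 ± 1.5, 0.812 ± 0.348 and 34.9 ± 5.36 TPM in cmt2, cmt3a and cmt2/cmt3a. LOC_Os10g24004 held 1.10 ± 0.751 TPM in cmt2/cmt3a, and LOC_Os06g11490 46.6 ± 2.68, 52.1 ± 0.976 and 32.5 ± 1.40 TPM in the 3 lines. In total 7660 loci had an interaction, 6347 of them positive and 1313 negative, with a median of 0.45 over all tested loci, and after rescaling 3534 and 3382. The call of OsNRPD1a was lost with the length trend removed (0.86) and that of OsRBCS3 without WT set 1 replicate 3 (-0.99).

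Directly against cmt2, cmt2/cmt3a had higher OsMADS14, OsMADS18 (56.3 ± 3.41 against 23.1 ± 1.36 TPM), OsWRKY45 (39.0 ± 1.75 against 15.4 ± 1.54 TPM), Cht1 (6.50 ± 0.349 against 2.27 ± 0.406 TPM) and SLR1 (SD, n = 3). LOC_Os02g53240 held 186 ± 28.3 against 0.609 ± 0.266 TPM and LOC_Os04g36580 120 ± 10.4 against 0.840 ± 0.344 TPM, while LOC_Os12g14440 was lower, at 0.652 ± 0.287 against 36.3 ± 3.35 TPM. Against cmt3a, OsMADS14, OsWRKY45, SLR1, SD1, OsROS1a and OsRCA were higher. Also higher were BRI1, the brassinosteroid receptor gene (9.17 ± 0.194 against 2.73 ± 0.517 TPM), and GID1, the gibberellin receptor gene (35.7 ± 2.58 against 14.7 ± 1.39 TPM). LOC_Os03g02470 held 63.4 ± 9.70 against 0.746 ± 0.205 TPM and LOC_Os06g38150 67.6 ± 10.2 against 2.13 ± 0.445 TPM, while LOC_Os04g43090 was listed at 0 against 9.16 ± 1.82 TPM. LOC_Os09g30340 held 19.5 ± 33.8 against 825 ± 486 TPM, and its call was lost without cmt3a replicate 2 (log2 change -7.38) or 3 (-7.08), without cmt2/cmt3a replicate 1 (-6.53) or 3 (-6.53) and with no filter on low values. The counts were 1527 higher and 167 lower against cmt2, and 2873 and 116 against cmt3a, with the median shifted by 0.30 and 0.33. After rescaling they were 616 and 441, and 1237 and 546, and the calls of SLR1 (0.64), OsWRKY45 (0.92), Cht1 (0.92) and OsMADS18 (0.88) against cmt2 and of OsRCA (0.63), OsWRKY45 (0.83), SD1 (0.83) and GID1 (0.84) against cmt3a were lost. Those calls were also lost with the length trend removed, except that of OsWRKY45 against cmt2, and with them that of OsROS1a against cmt3a (0.75). The call of SLR1 against cmt2 was lost without cmt2 replicate 1 (0.92) or cmt2/cmt3a replicate 2 (0.99), and that of SD1 against cmt3a without cmt3a replicate 3 (0.95).

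In cmt2/drm2 5 of 11 defence genes rose and none fell. The list was called higher (adjusted p = 0.0186), but not with an estimated correlation (adjusted p = 0.0842 with an estimated correlation) or with a pseudocount of 0.1. JIOsPR10 rose from 0.228 ± 0.199 and 0.0875 ± 0.0890 TPM in WT sets 1 and 2 to 10.0 ± 0.851 TPM in cmt2/drm2 (SD, n = 3, adjusted p = 3.46e-14). Cht1 rose from 1.72 ± 0.123 and 3.08 ± 0.441 TPM to 30.1 ± 1.47 TPM, OsPR1b from 5.21 ± 5.34 and 3.73 ± 0.905 TPM to 36.2 ± 3.71 TPM and OsWRKY45 to 31.1 ± 0.906 TPM. The small heat shock genes HSP16.9B, from 0.368 ± 0.202 and 1.13 ± 0.750 TPM to 4.59 ± 0.528 TPM, and HSP17.4B, from 1.3 ± 0.256 and 3.58 ± 0.448 TPM to 8.27 ± 0.680 TPM, rose, which made 2 of 8 heat shock genes. OsMADS58 rose to 2.28 ± 0.419 TPM. LOC_Os07g11100 rose from 2.12 ± 0.509 and 2.09 ± 0.781 TPM to 145 ± 13.7 TPM. LOC_Os12g38300 rose from 0.169 ± 0.292 and 0.0978 ± 0.169 TPM to 52.0 ± 1.03 TPM. LOC_Os11g06980 fell to 0.714 ± 0.152 TPM. LOC_Os10g09300, with 66.3 ± 17 and 16.5 ± 4.19 TPM in the WT sets, was listed at 0 in each cmt2/drm2 library. In total 605 loci rose and 187 fell. The HSP17.4B call was lost without WT set 2 replicate 1 (log2 change 0.95), without cmt2/drm2 replicate 3 (0.97) and after rescaling (0.95).

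In cmt3a/drm2 4 of 11 defence genes fell and 1 rose, and the list was not called (adjusted p = 0.449, and adjusted p = 0.62 with an estimated correlation). OsPR10b fell from 7.71 ± 2.34 and 21.4 ± 2.80 TPM in WT sets 1 and 2 to 1.35 ± 0.578 TPM in cmt3a/drm2 (SD, n = 3, adjusted p = 1.52e-09). OsPR1b fell to 0.594 ± 0.489 TPM and PBZ1 from 81.0 ± 31.4 and 192 ± 27.9 TPM to 32.2 ± 2.89 TPM, while Cht1 rose to 8.95 ± 0.651 TPM. Of the phytoalexin genes, the diterpene synthase gene OsKSL7 rose from 0.0219 ± 0.0380 and 0.0228 ± 0.0394 TPM to 2.29 ± 0.400 TPM and OsCPS4 fell to 0.283 ± 0.232 TPM. OsMADS58 rose to 18.7 ± 0.478 TPM (adjusted p = 6.85e-18). LOC_Os01g01660 (chromosome 1, 327128 to 328451) rose from 2.52 ± 0.390 and 2.65 ± 0.461 TPM to 808 ± 18.0 TPM and LOC_Os12g38300 to 199 ± 8.26 TPM. LOC_Os11g06980 fell to 0.0429 ± 0.0436 TPM and LOC_Os11g41710 to 0.499 ± 0.178 TPM. In total 849 loci rose and 320 fell. The PBZ1 call was lost without WT set 1 replicate 1 (log2 change -0.999), and that of OsPR1b when only cmt3a/drm2 and the WT sets were fitted.

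Several named genes lowered in cmt2 and cmt3a were higher in cmt2/drm2 and cmt3a/drm2. A batch shared by the cmt2 and cmt3a libraries would also give such differences, so they are not shown to come from DRM2 loss. OsRCA held 12038 ± 325 TPM in cmt2/drm2 against 4487 ± 275 TPM in cmt2, and 11827 ± 205 TPM in cmt3a/drm2 against 3148 ± 111 TPM in cmt3a (SD, n = 3, adjusted p = 4.35e-17 and 5.75e-20). SLR1 held 90.3 ± 2.83 and 91.8 ± 3.77 TPM, BRI1 15.9 ± 0.677 against 4.52 ± 0.910 TPM and 13.8 ± 0.146 against 2.73 ± 0.517 TPM, and OsAGO4b 40.4 ± 1.09 and 36.6 ± 2.30 TPM, all higher than in cmt2 or cmt3a. OsNRPE1, a subunit gene of RNA polymerase V, was higher in cmt2/drm2, with 16.0 ± 0.648 against 5.74 ± 0.981 TPM. GID1 (59.6 ± 3.17 against 14.7 ± 1.39 TPM), D14 (477 ± 3.24 against 147 ± 4.85 TPM) and OsNRPD1a (8.12 ± 0.749 against 2.71 ± 0.411 TPM) were higher in cmt3a/drm2. DTH8 was lower, at 0.873 ± 0.281 TPM in cmt2/drm2 and 0.920 ± 0.178 TPM in cmt3a/drm2, and OsGA20ox1 was lower in cmt2/drm2, at 7.11 ± 0.458 TPM. Cht1 and OsPR1b were higher in cmt2/drm2 than in cmt2 (2.27 ± 0.406 and 3.13 ± 0.324 TPM). OsPR10b was lower in cmt2/drm2 (3.72 ± 0.272 against 21.1 ± 1.83 TPM) and in cmt3a/drm2 (1.35 ± 0.578 against 29.1 ± 2.86 TPM), as was PBZ1 in the latter (32.2 ± 2.89 against 348 ± 18.0 TPM). In cmt2/drm2, LOC_Os07g11100 (listed at 0 in cmt2) and LOC_Os06g29679 (47.1 ± 2.77 against 0.0647 ± 0.0736 TPM) were higher, and LOC_Os02g11770 (1.68 ± 0.369 against 156 ± 14.1 TPM) and LOC_Os10g24004 (0.169 ± 0.0852 TPM) lower. In cmt3a/drm2, LOC_Os12g38300 (1.86 ± 1.63 TPM in cmt3a) and LOC_Os12g31860 (328 ± 44.7 against 3.22 ± 0.399 TPM) were higher, and LOC_Os09g10340 (1.34 ± 0.298 against 128 ± 3.22 TPM) and LOC_Os07g25050 (0.252 ± 0.30 against 58.2 ± 2.96 TPM) lower. The counts were 3540 higher and 1238 lower against cmt2, and 4435 and 1747 against cmt3a, with the median shifted by 0.27 and 0.21, and after rescaling 1802 and 2239, and 3096 and 2900. Rescaling ended the cmt2/drm2 calls of SLR1 (0.99) and OsNRPE1 (0.99), and removal of the length trend those of OsNRPE1 (0.47), OsAGO4b (0.74 and 0.75) and OsNRPD1a (0.77).

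The triple mutant was compared with WT as 2 sets, to ask what changes once all 3 genes are lost. Small heat shock genes were among the loci that rose most. HSP17.4B rose from 1.3 ± 0.256 and 3.58 ± 0.448 TPM in WT sets 1 and 2 to 3299 ± 242 TPM in triple mutant set 1 and 2205 ± 136 TPM in set 2 (SD, n = 3, adjusted p = 8.66e-24 for both sets together). HSP18.0 rose from 0.499 ± 0.664 and 1.83 ± 0.611 TPM to 1498 ± 51.8 and 933 ± 69.8 TPM. HSP17.7 rose from 7.34 ± 1.21 and 10.8 ± 1.89 TPM to 1297 ± 67.3 and 1190 ± 50.9 TPM, and HSP16.9B from 0.368 ± 0.202 and 1.13 ± 0.750 TPM to 214 ± 25.0 and 317 ± 23.0 TPM. Of 8 heat shock genes 6 rose in each set (adjusted p = 0.00669 in set 1 and 0.00345 in set 2, and adjusted p = 0.0653 and 0.0605 with an estimated correlation).

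**Figure D2:**
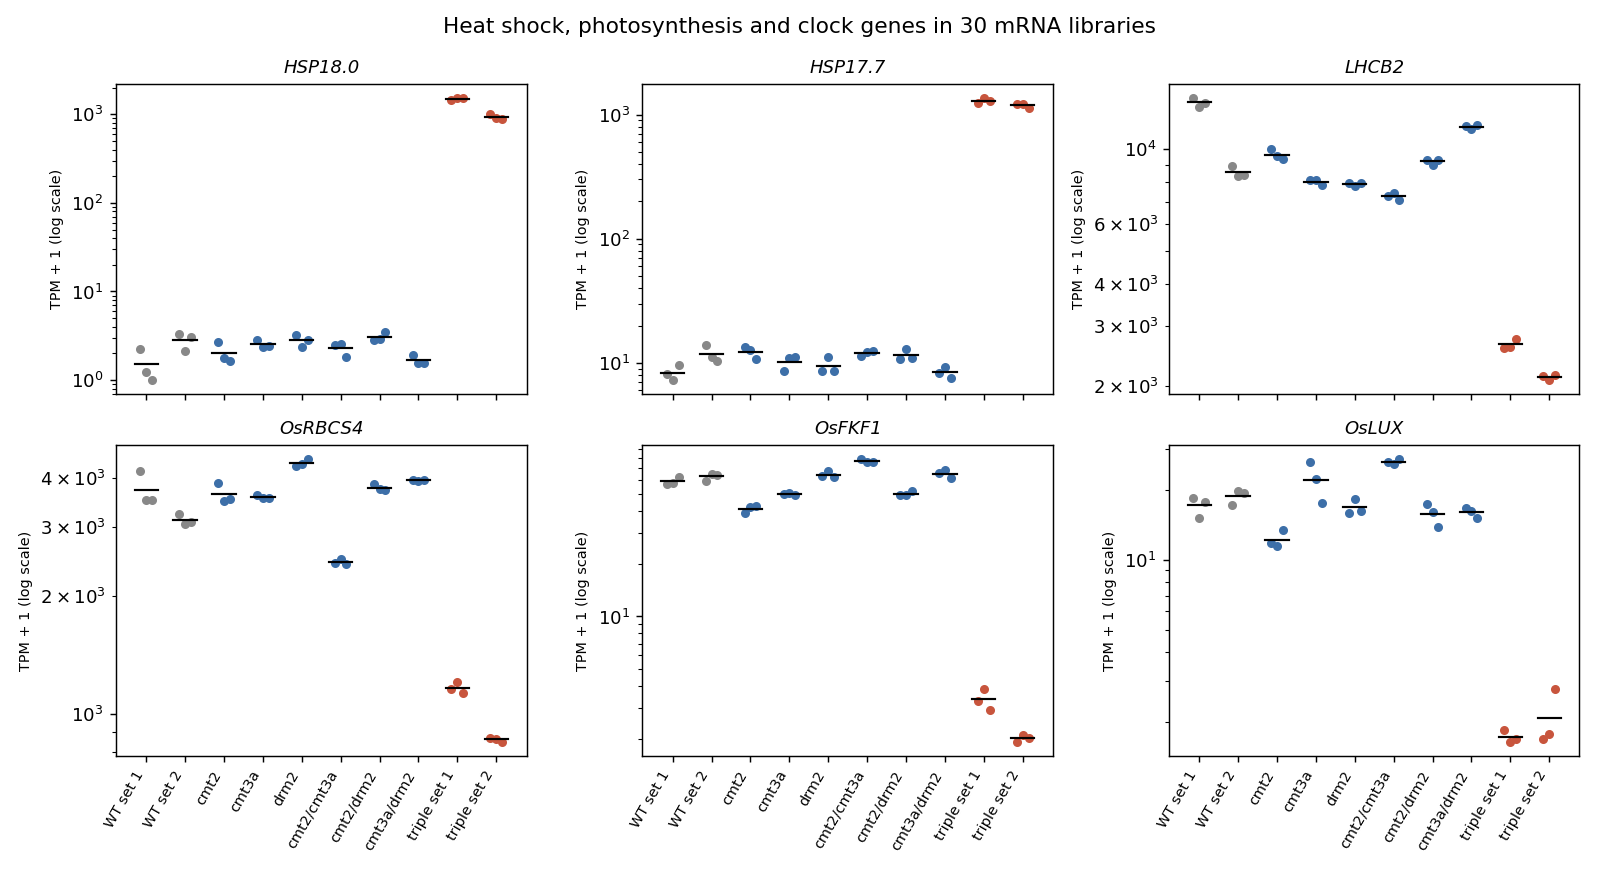
Levels of 6 genes in each of the 30 mRNA libraries (points, TPM + 1 on a log scale) with the mean of the 3 libraries of each group (lines), for WT (grey), other mutants (blue) and the triple mutant (red). HSP18.0 stands at 1498 and 933 TPM in triple mutant sets 1 and 2, LHCB2 at 2649 and 2122 TPM and OsFKF1 at 2.36 and 1.02 TPM.

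Clock and photosynthesis genes fell in both triple mutant sets. OsFKF1, an evening gene of the clock, fell from 58.1 ± 2.91 and 62.1 ± 3.11 TPM in the WT sets to 2.36 ± 0.469 TPM in set 1 and 1.02 ± 0.0898 TPM in set 2 (SD, n = 3). OsLUX fell from 16.2 ± 1.78 and 17.9 ± 1.35 TPM to 0.726 ± 0.104 and 1.07 ± 0.603 TPM. OsPRR1 fell from 77.7 ± 8.31 and 84.3 ± 13.0 TPM to 8.01 ± 0.954 and 11.5 ± 0.717 TPM, and OsPRR95 from 943 ± 36.7 and 851 ± 160 TPM to 114 ± 13.9 and 129 ± 21.8 TPM. Of 10 clock genes 7 fell in set 1, and 6 fell and 1 rose in set 2 (adjusted p = 0.000799 and 0.000173, and adjusted p = 0.464 and 0.413 with an estimated correlation). The light-harvesting gene CAB2R fell from 27347 ± 2712 and 22373 ± 3607 TPM to 4965 ± 134 and 5031 ± 236 TPM. LHCB2 fell from 13741 ± 428 and 8539 ± 342 TPM to 2649 ± 95.1 and 2122 ± 37.9 TPM, and LHCB5 from 8356 ± 719 and 4589 ± 299 TPM to 1816 ± 56.3 and 1426 ± 74.0 TPM. The Rubisco small subunit gene OsRBCS4 fell from 3730 ± 386 and 3126 ± 93.6 TPM to 1166 ± 38.5 and 860 ± 8.95 TPM. Of 12 photosynthesis genes 8 fell in each set (adjusted p = 7.86e-06 and 1.41e-08, and adjusted p = 0.196 and 0.0842 with an estimated correlation).

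Defence genes rose in both triple mutant sets, 10 of 11 in set 1 and 7 in set 2. OsPR1b rose from 5.21 ± 5.34 and 3.73 ± 0.905 TPM to 885 ± 23.4 TPM in set 1 and 107 ± 3.43 TPM in set 2 (SD, n = 3). OsWRKY76 rose from 0.174 ± 0.259 and 0.251 ± 0.266 TPM to 15.7 ± 0.984 and 6.45 ± 0.261 TPM. OsWRKY62 rose from 0.0367 ± 0.0636 and 0.0905 ± 0.109 TPM to 7.73 ± 2.19 and 7.66 ± 0.682 TPM, and OsWRKY45 from 4.78 ± 0.42 and 7.34 ± 0.220 TPM to 51.2 ± 6.72 and 60.4 ± 0.805 TPM. The list was called in both (adjusted p = 0.000108 and 0.0192, and adjusted p = 0.0108 and 0.0842 with an estimated correlation). In set 1 alone the phytoalexin list was called higher, with 7 of 10 genes higher and 1 lower (adjusted p = 0.0494, and adjusted p = 0.261 with an estimated correlation), and the senescence list, with 4 of 8 higher (adjusted p = 0.0176, and adjusted p = 0.523 with an estimated correlation). The phytoalexin call was also lost with a pseudocount of 0.1. NOMT, which makes the flavonoid phytoalexin sakuranetin, stood at 68.5 ± 2.18 TPM in set 1 and was listed at 0 in all 6 WT libraries. OsKSL7 rose in set 1 to 43.9 ± 2.15 TPM, OsMAS, of momilactone synthesis, to 35.0 ± 4.21 TPM and CYP99A2 from 0.245 ± 0.0788 and 0.124 ± 0.0705 TPM to 5.53 ± 0.255 TPM. In set 2 OsCPS4 fell to 0.206 ± 0.0807 TPM and CYP99A3 from 3.09 ± 0.599 and 4.77 ± 0.495 TPM to 0.801 ± 0.0738 TPM.

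Of the other named genes, SGR rose from 1.97 ± 0.126 and 8.15 ± 0.925 TPM to 140 ± 7.29 TPM in triple mutant set 1 and 39.9 ± 2.1 TPM in set 2 (SD, n = 3). In set 1 OsNAP rose to 99.8 ± 5.78 TPM, NYC3 from 78.6 ± 9.42 and 75.5 ± 12.1 TPM to 220 ± 15.1 TPM and Osl2 from 42.0 ± 1.98 and 54.6 ± 2.49 TPM to 140 ± 4.48 TPM. In set 2 NYC1, a chlorophyll b reductase gene, fell from 175 ± 6.93 and 153 ± 14.3 TPM to 71.0 ± 3.66 TPM. SLR1 fell to 21.9 ± 1.31 and 30.6 ± 1.63 TPM, and SD1 rose in set 2 to 157 ± 6.80 TPM. The floral promoter gene OsMADS50 fell from 92.0 ± 4.12 and 83.8 ± 2.41 TPM to 21.7 ± 0.810 and 27.2 ± 0.841 TPM. Ehd1, listed at 0 in all 6 WT libraries, stood at 1.32 ± 0.510 and 2.45 ± 0.402 TPM. OsDCL1, which encodes a Dicer protein, fell from 20.5 ± 0.715 and 21.6 ± 5.79 TPM to 6.85 ± 0.196 and 8.90 ± 0.358 TPM. Among markers of other organs, OsMADS58 rose to 5.73 ± 1.23 and 25.6 ± 1.62 TPM and Lsi1 from 4.24 ± 1.2 and 4.72 ± 0.555 TPM to 45.3 ± 2.57 and 40.6 ± 1.28 TPM. The root metal transporter genes fell, OsIRT1 from 2.18 ± 0.887 and 2.52 ± 0.703 TPM to 0.203 ± 0.176 and 0.0414 ± 0.0422 TPM, and OsNramp5 from 1.2 ± 0.497 and 3.22 ± 0.305 TPM to a listed 0 in each library of both sets. The OsNramp5 call was lost without WT set 1 replicate 2 (log2 change -0.92), and that of Ehd1 in set 1 with the length trend removed (0.96).

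The other lists were not called in either triple mutant set. Of 12 hormone and architecture genes 3 fell in set 1, and 2 rose and 1 fell in set 2. Of 9 flowering genes 1 rose and 2 fell, then 1 rose and 1 fell, and of 12 small RNA pathway genes 1 fell in each set. Of 5 demethylation and remodelling genes 1 fell in set 1, and of 4 DNA methyltransferase genes 1 rose in each. Of 5 panicle markers 2 rose in set 1 and 1 in set 2, of 3 root markers 1 rose and 2 fell in each, of 3 seed markers none was called, and the single meristem marker tested, FON1, was called lower in set 1. For the root markers in set 1 the median was -1.46 and the mean 0.02, while the test pointed down (adjusted p = 0.696). The hormone list also pointed down in both sets (adjusted p = 0.557 and 0.866), with medians of 0.04 and 0.35 and means of -0.18 and 0.22, and the small RNA pathway list in set 2 (adjusted p = 0.674), with a median of 0.0068 and a mean of -0.0072. In all 120 tests of a list in a mutant, the counts of called members adjusted over the list alone were the same as those over all genes tested.

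In total 6413 loci were called in triple mutant set 1, of which 4335 rose and 2078 fell, and 5290 in set 2, of which 3845 rose and 1445 fell. Both sets together gave 2905 loci that rose and 1234 that fell. LOC_Os04g28420 (chromosome 4, 16813848 to 16817974) rose to 3941 ± 246 TPM in set 1 and 3376 ± 16.6 TPM in set 2, against 0.892 ± 0.392 TPM in WT set 2 and 0 in each library of WT set 1 (SD, n = 3). LOC_Os01g06310 (chromosome 1, 2999576 to 3001204) rose from 0.0770 ± 0.0672 and 0.408 ± 0.183 TPM to 1050 ± 38.5 and 805 ± 52.3 TPM. LOC_Os07g34570 (chromosome 7, 20724563 to 20726098) fell from 9261 ± 490 and 8266 ± 610 TPM to 10.0 ± 1.40 and 23.6 ± 0.753 TPM, and LOC_Os08g13440 to 1.14 ± 0.384 and 0.844 ± 0.467 TPM. The median of all tested loci shifted by 0.13 in set 1 and 0.24 in set 2, and after rescaling the split in set 2 was 3092 higher and 1866 lower. The triple mutant libraries stood apart on the first principal component, which held 51.5% of the variance.

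The triple mutant sets were also compared with each other, since they share a genotype by label. Of 10 phytoalexin genes 9 were called lower in set 2 than in set 1, and of 11 defence genes 7, with none higher, though the lists were not tested here. Lower were NOMT (0.271 ± 0.202 against 68.5 ± 2.18 TPM), OsKSL7 (0.547 ± 0.177 against 43.9 ± 2.15 TPM), OsMAS (0.999 ± 0.585 against 35.0 ± 4.21 TPM) and OsCPS4 (0.206 ± 0.0807 against 8.84 ± 0.501 TPM) (SD, n = 3). JIOsPR10 held 0.675 ± 0.232 against 42.0 ± 3.13 TPM, OsPR1a 0.638 ± 0.237 against 18.6 ± 3.03 TPM, Cht1 15.4 ± 1.02 against 164 ± 30.4 TPM and OsPR1b 107 ± 3.43 against 885 ± 23.4 TPM, while OsWRKY45 and OsWRKY62 were not called. Of the senescence genes, OsNAP (21.0 ± 1.33 against 99.8 ± 5.78 TPM), SGR, NYC1 (71.0 ± 3.66 against 235 ± 4.73 TPM) and OsNAC2 (1.97 ± 0.203 against 6.53 ± 0.555 TPM) were lower in set 2. SD1 (157 ± 6.80 against 58.6 ± 13.2 TPM) and OsMADS58 were higher. LOC_Os07g05360 held 1726 ± 91.1 against 95.7 ± 7.68 TPM, LOC_Os03g03330 16.3 ± 0.376 against 0.224 ± 0.273 TPM, LOC_Os03g56930 0.286 ± 0.269 against 128 ± 20.2 TPM and LOC_Os01g42860 13.1 ± 3.20 against 1127 ± 166 TPM. In total 581 loci were higher and 1346 lower in set 2, and after rescaling 345 and 1531, with the median shifted by 0.13.

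Across all 10 groups, an additive model of the 3 losses asked which loci follow each lost gene whatever the other genotypes. Loss of CMT3a called 74 higher and 7 lower loci, of which 72 were also called in cmt3a itself. The cmt3a and WT groups are part of the model, so this overlap is no separate check. LOC_Os02g22250 (chromosome 2, 13265887 to 13267486) held 48.0 ± 5.14 to 251 ± 3.90 TPM in the 5 groups without CMT3a and at most 0.0324 ± 0.0562 TPM in the 5 with it (SD, n = 3, log2 effect 6.45 ± 0.38, adjusted p = 0.00019). LOC_Os04g36580 (chromosome 4, 22067484 to 22072320), chosen after its values were seen, held 120 ± 10.4 to 247 ± 26.5 TPM without CMT3a and at most 3.25 ± 1.34 TPM with it. LOC_Os07g48020 (chromosome 7, 28673754 to 28675433) held at most 2.85 ± 0.445 TPM without CMT3a and at least 13.6 ± 1.69 TPM with it. Of the 74 higher loci, 52 stayed under 1 TPM in all 5 groups with CMT3a and 13 were listed at 0 there. The calls of LOC_Os02g53240 (effect 5.91 ± 0.98, 5.19 to 6.63 with 1 group left out) and LOC_Os07g32710 (-2.13 ± 0.35, -2.22 to -1.82) did not withstand leaving out WT set 1, drm2 or most other groups, no filter on low values (5.91 and -2.13) or removal of the length trend (5.78 and -2.17). The former was also lost with a pseudocount of 0.1 (7.18) and the latter after rescaling (-2.14), and both in fits with fewer groups. The total was 18 without cmt2/drm2 and 83 without triple mutant set 1, and 9 of 10 such fits called fewer than 81.

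**Figure D3:**
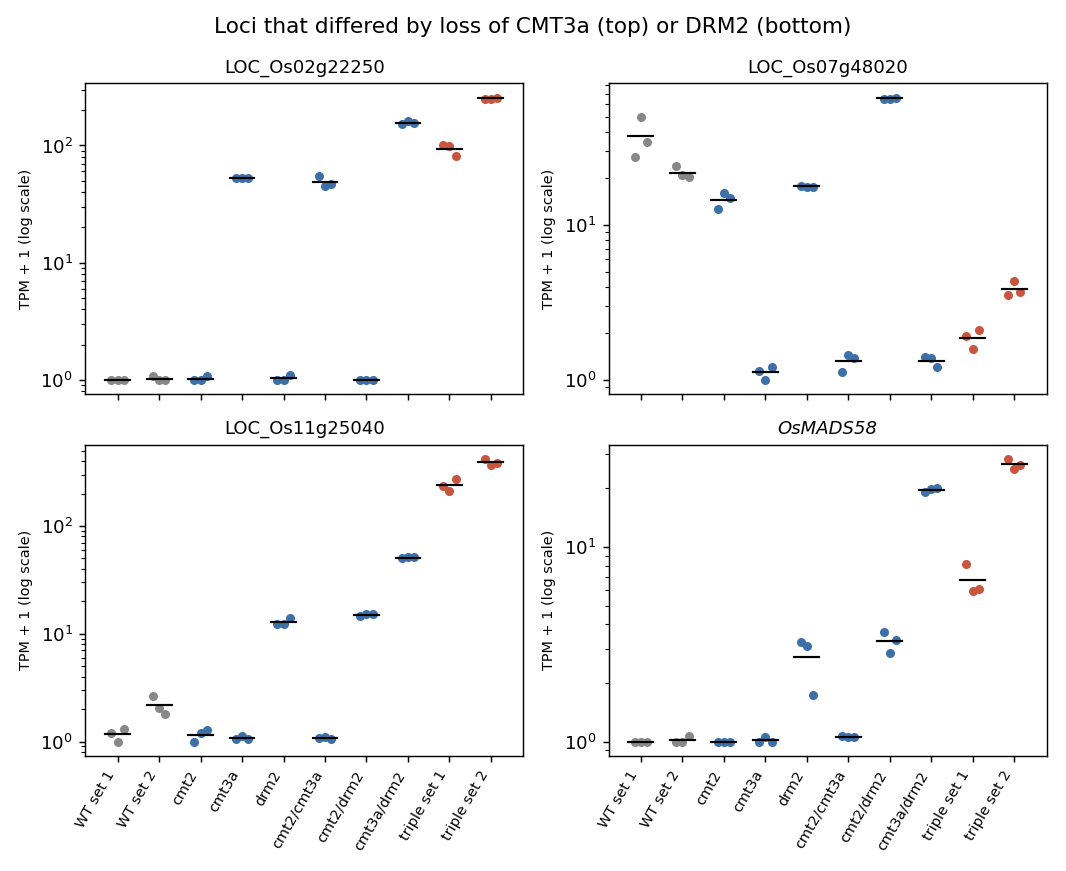
Levels of 4 loci in each of the 30 mRNA libraries (points, TPM + 1 on a log scale) with the mean of each group (lines), for WT (grey), other mutants (blue) and the triple mutant (red). LOC_Os02g22250 stands at 48.0 TPM or more in each group without CMT3a, and OsMADS58 at 1.70 TPM or more in each group without DRM2.

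Loss of DRM2 called 146 higher and 71 lower loci in this model, and after rescaling 126 and 102. Of those called before rescaling, 164 were also called in drm2, which is part of the model too. OsMADS58, a panicle marker listed at or near 0 with DRM2, held 1.70 ± 0.837 TPM in drm2, 2.28 ± 0.419 TPM in cmt2/drm2, 18.7 ± 0.478 TPM in cmt3a/drm2 and 5.73 ± 1.23 and 25.6 ± 1.62 TPM in the triple mutant sets (SD, n = 3, effect 2.71 ± 0.52, adjusted p = 0.0488). LOC_Os06g29679 (chromosome 6, 17029405 to 17030321) held 7.13 ± 1.2 to 68.2 ± 2.06 TPM without DRM2 and at most 0.290 ± 0.187 TPM with it. LOC_Os11g25040 (chromosome 11, 14267737 to 14268968) held 11.9 ± 0.972 to 390 ± 23.5 TPM and at most 1.16 ± 0.419 TPM. LOC_Os11g06980 held at most 0.714 ± 0.152 TPM without DRM2 and at least 6.80 ± 0.191 TPM with it, and LOC_Os09g10340 at most 6.41 ± 0.548 TPM and at least 13.0 ± 9.91 TPM. Of the 146 higher loci, 54 stayed under 1 TPM in all 5 groups with DRM2 and 5 were listed at 0 there. The total was 64 without cmt2 and 186 without WT set 1, and the median of all tested loci shifted by 0.21. The OsMADS58 call was lost in each fit without 1 group (effects 2.38 to 3.19), after rescaling (2.63), with the length trend removed (2.34) and with no filter on low values (2.71), and that of LOC_Os09g10340 without WT set 2, either triple mutant set, cmt2, cmt3a or a double mutant (-4.88 to -3.48), with a pseudocount of 0.1 (-5.60) and with no filter (-4.53). The call of LOC_Os11g25040 was lost without cmt2, cmt3a or cmt2/cmt3a (5.20, 4.83 and 4.38) and with no filter (5.18). Without both the cmt2 and cmt3a lines these 3 calls and that of LOC_Os06g29679 (4.97) were lost. Loss of CMT2 called no locus in limma at an adjusted p under 0.05, with 538 loci at an unadjusted p under 0.05. Adjusted over the list alone, 2 of 11 defence genes were called higher by CMT2 loss, and 1 DNA methyltransferase gene and 1 root marker higher and 1 flowering gene lower by DRM2 loss, against 0 over all genes tested.

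Small RNAs were compared between the 5 libraries with a locus mutated and the 5 with it intact. The 24 nt class made up 72.1% (95% Wilson interval 72.1 to 72.2) and 70.5% (70.4 to 70.5) of the alignments in the WT libraries and 55.1% (55.0 to 55.2) and 61.9% (61.8 to 62.0) in the triple mutant. The 21 nt class made up 4.89% (4.86 to 4.92) and 5.26% (5.23 to 5.29) in WT and 11.1% (11.0 to 11.2) and 9.91% (9.86 to 9.96) in the triple mutant. In the other 6 libraries the 24 nt share lay between 68.7% (68.6 to 68.8) and 74.3% (74.2 to 74.4). No share passed the exact permutation test for any lost gene after adjustment (smallest adjusted p = 0.25 of 9 tests, two-sided exact permutation), where a difference in 1 share alone can reach 0.0714 at best. The largest difference was in 24 nt alignments by loss of CMT3a, 66.3 ± 7.80% against 72.2 ± 1.43% (SD, n = 5, exact p = 0.151), which went from -5.90 to -3.09 percentage points without triple mutant library 1 and to -0.67 without both triple mutant libraries. The intervals cover counting error only, and each alignment is counted once, so shares also move with depth.

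**Figure D4:**
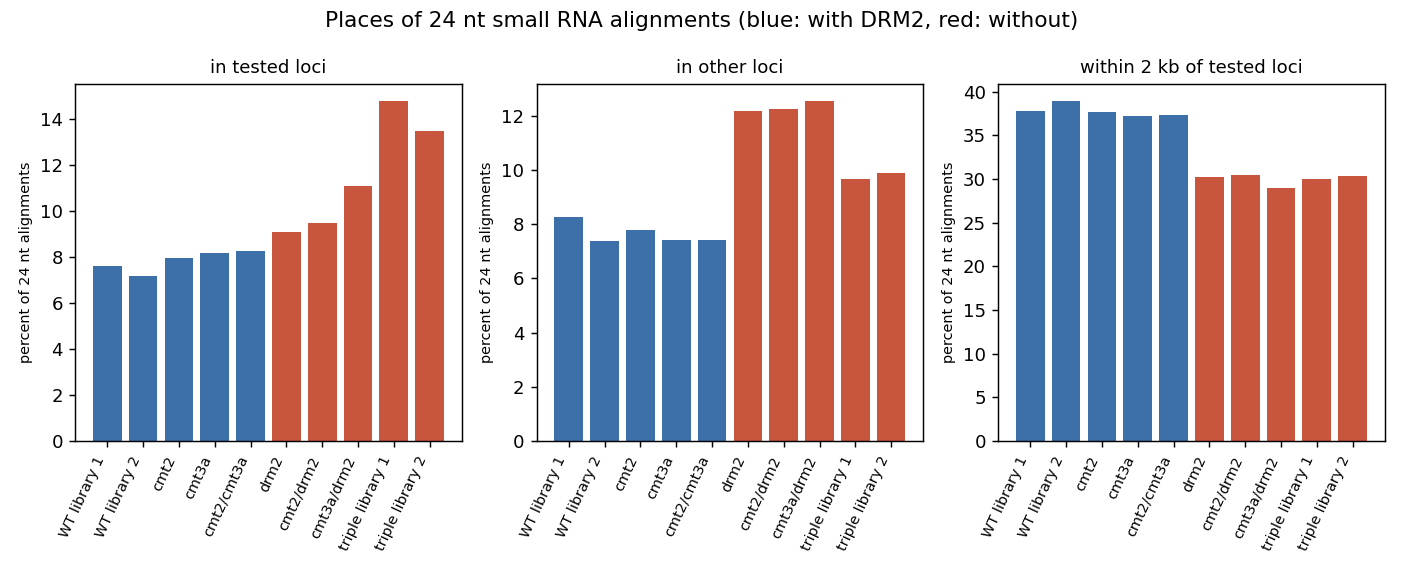
Percent of 24 nt alignments in tested loci, in other annotated loci and within 2 kb of tested loci, in each of the 10 small RNA libraries (bars), with DRM2 (blue) and without it (red). The share within 2 kb of tested loci lies between 37.2 and 39.0% with DRM2 and between 29.0 and 30.4% without it.

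The places of 24 nt alignments followed DRM2. Within 2 kb of tested loci lay 30.0 ± 0.576% of them without DRM2 and 37.8 ± 0.694% with it, lower in 5 of 5 libraries (SD, n = 5, exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0317 of 12 tests). Inside tested loci lay 11.6 ± 2.48% without DRM2 and 7.83 ± 0.435% with it, and inside other loci 11.3 ± 1.40% and 7.65 ± 0.376%, both higher in 5 of 5 libraries (exact permutation, adjusted p = 0.0317). Elsewhere in the genome the shares were 47.1 ± 1.16% and 46.7 ± 0.356% (exact permutation, adjusted p = 0.698). Loss of CMT2 or CMT3a gave no place a difference that passed the adjustment (smallest adjusted p = 0.262, exact permutation). This division of the genome was chosen after the data were seen.

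In bins of 10 kb, 10726 of 29777 differed in 24 nt alignments by loss of DRM2, 5166 higher and 5560 lower (limma, Benjamini-Hochberg), and 2579 with the stricter filter. A tested locus lay in 77.4% of the lower bins and 51.4% of the higher ones, against 61.4% of all bins. The bin on chromosome 6 from 5630001 to 5640000 held 2.47 ± 2.71 CPM (alignments scaled to the library total) without DRM2 and 45.6 ± 12.1 with it (SD, n = 5), and that on chromosome 2 from 31220001 to 31230000 held 1.45 ± 1.31 and 34.6 ± 10.2. The bin on chromosome 9 from 2310001 to 2320000 held 26.2 ± 5.39 without DRM2 and 1.32 ± 1.85 with it. Loss of CMT3a called 326 higher and 1287 lower bins, and 518 and 797 with TMM scaling, in all 461 with the stricter filter and 1047 once libraries were thinned to equal size. The libraries without CMT3a were shallower, at 661311 to 1235584 alignments against 981484 to 2366085. Loss of CMT2 called none in limma, with 1483 at an unadjusted p under 0.05. At the 74 loci higher without CMT3a, 21 nt alignments averaged 8.24 ± 8.64 CPM without CMT3a and 0.412 ± 0.193 with it, higher in 5 of 5 libraries (SD, n = 5, exact permutation, adjusted p = 0.0476 of 60 tests). Triple mutant library 2 held 20.9, and without it the mean was 5.08. In the libraries without CMT3a 5 of these loci held 58.0 to 89.7% of the alignments, and the median locus held 0 in 4 of 5. In the other tested loci they averaged 1.75 ± 0.959 without CMT3a and 0.780 ± 0.157 with it (exact permutation, adjusted p = 0.196). Within 2 kb of the 71 loci lower without DRM2, 24 nt alignments averaged 12.9 ± 0.894 CPM without DRM2 and 27.0 ± 2.41 with it, lower in 5 of 5 (exact permutation, adjusted p = 0.0476). Within 2 kb of the 146 higher loci they also averaged less, 13.6 ± 1.21 against 19.5 ± 1.09, as they did near other tested loci, 10.5 ± 1.13 against 14.3 ± 0.167.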

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

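The interaction of cmt2 and cmt3a and the comparison of the triple mutant sets were planned, and the test for a few loci that take most alignments was chosen before its result was seen. The other tests of this part, among them those of the organelle chromosomes, were chosen only after the result was seen. The interaction of cmt2 and cmt3a was called at 7660 loci (7300 to 7863 with 1 of 15 libraries left out), which a batch shared by the cmt2 and cmt3a libraries would also give. The triple mutant sets, of the same genotype by label, differed from each other at 1927 loci (1707 to 1956 with 1 of 6 libraries left out). In alignments outside the comparisons, small RNAs on the mitochondrial chromosome made up 0.165 ± 0.0566% of a library without DRM2 and 0.0461 ± 0.0116% with it, higher in 5 of 5 libraries (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0476 of 6 tests). The drm2 library held only 0.0744%, little above the 0.0640% of cmt2/cmt3a, the highest with DRM2. It also had the most alignments, 2366085, and shares of distinct alignments move with depth. Among the 5 libraries with CMT2, cmt3a/drm2 with 0.180% was marked as apart. Its gap to the nearest was 0.712 of their range, against a critical value of 0.71. It did not stand apart from cmt2/drm2, with 0.158%, or from triple mutant libraries 1 and 2, with 0.228 and 0.185%. Such a mark came in 1 of 54 groups of 5 libraries, and chance marks about 1 in 20 groups. No explanation was tested for the mitochondrial alignments or for the difference between the triple mutant sets.

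In cmt2 and cmt3a 2307 and 3870 loci were called, most of them lower before rescaling, and many returned towards WT in cmt2/cmt3a. A bias with locus length is argued against as the cause of the number of calls, since after removal of the length trend the line with fewer calls still had 4.45 times those between the WT sets. It may account for part of the excess of lower calls, since lower calls made up 43.1% of the calls in cmt2 and 54.6% in cmt3a among the 25% shortest loci and 89.3 and 91.6% among the longest, but 62.7 and 69.4% of all calls once the trend was removed and the shift of each library kept, while the part of the authors' scaling to TPM stays open, because rescaling centres each library, which turned the split in cmt2 (1221 higher and 819 lower) and evened it in cmt3a (1833 and 1803). Loss of CMT2 or CMT3a whatever the other gene is argued against as the whole account, because after rescaling 26.1% of the loci called the same way in both lines were called that way in cmt2/cmt3a, 349 of 921 higher and 89 of 756 lower, and 0 the opposite way (medians 1.65 and 1.70 against 1.00, and -1.42 and -1.80 against -0.70). A batch shared by the cmt2 and cmt3a libraries and an effect of the single mutants cannot be told apart, since the 6 libraries lay 33.9 beyond all others on the second principal component and genotype and batch would coincide, and an effect of each single loss that needs the other gene intact stays open too.

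In both triple mutant sets the heat shock list was called higher (6 of 8 genes) and the photosynthesis (8 of 12) and clock lists (7 of 10 in set 1, 6 in set 2 with 1 higher) lower, but none of these 6 calls held with an estimated correlation (adjusted p = 0.0605 to 0.464). After rescaling, the median of each list still lay in the same direction in both sets, the smallest at 1.32 on the log2 scale. This cannot decide on the authors' scaling to TPM, since rescaling changes each library by 1 factor. It moved the median of all tested loci only from 0.13 to 0.061 in set 1 and from 0.24 to 0.055 in set 2. Such a factor is too small to undo list changes of this size, and other effects of the scaling stay open. For the clock genes alone, leaves taken at another time of day may be the reason, as the morning gene OsLHY, chosen after its values were seen, moved up by 0.89 or more on the log2 scale against each WT set in each triple mutant set while evening genes fell, although its call in set 2 was lost after rescaling (0.80, and 0.76 in set 1) and with the length trend removed (0.93, and 0.82 in set 1). Loss of all 3 methyltransferases and a growth or sampling condition shared by both sets cannot be told apart, because with the sets set against different WT sets, in either assignment, at least 94.9% of the loci called in set 1 moved the same way in set 2, against at most 55.1% in 20 simulations with set 2 at the WT level, and either would give that. What keeps this open is that the labels give no harvest time, temperature record or batch for single libraries.

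The share of 24 nt alignments within 2 kb of tested loci was lower without DRM2, 29.0 to 30.4% against 37.2 to 39.0%. A difference in depth is argued against, as the range among the 5 libraries with DRM2 was 1.78 percentage points although their totals ran from 661311 to 2342705. A few loci are argued against, since 97.1% of the summed difference was left without the 228 loci with the most alignments. The difference was -7.89 percentage points without both triple mutant libraries, and the highest of the 3 libraries left without DRM2 was 30.4%. Loss of DRM2 is therefore a candidate explanation, as a hypothesis found and tested on the same libraries, while a batch that follows DRM2 was not tested.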

How the results depend on the processing

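Removal of the length trend, thinning to the smallest small RNA library, and fits without both triple mutant libraries, without both triple mutant sets or without the cmt2 and cmt3a lines were chosen after seeing the data, and the other settings before. Of 206 values of comparisons under other settings, 148 stayed within 1.5 times the value reported or on the same side of the threshold, 54 moved and 4 reversed. Of 2742 values of named genes, 2637 kept their direction and call, 97 lost the call and 8 gained it.

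With a pseudocount of 0.1 the calls were 3739 in cmt2, 1414 in drm2, 1878 in cmt2/cmt3a, 1421 in cmt2/drm2, 1939 in cmt3a/drm2, 1460 between the WT sets, 3104 between the triple mutant sets, 3607 and 5278 for cmt2/cmt3a against cmt2 and cmt3a, and 153 by CMT3a loss. Without a filter, CMT3a and DRM2 loss called 35 and 88. After rescaling, cmt2/cmt3a differed at 1057 loci from cmt2 and 1783 from cmt3a, and with the length trend removed at 916 and 1436. The adjusted p alone, which by construction calls more, gave 10831 in cmt2, 12629 in cmt3a, 4091 in drm2, 6513 in cmt2/cmt3a, 3787 in cmt2/drm2, 4369 in cmt3a/drm2, 14924, 14036 and 11311 in triple mutant set 1, set 2 and both, 8090 between the WT sets and 11843 between the triple mutant sets. It also gave 13164 and 14070 for cmt2/cmt3a against cmt2 and cmt3a, 15597 for cmt2/drm2 against cmt2, 16265 for cmt3a/drm2 against cmt3a and 13771 for the interaction. WT set 1 alone gave 4257 in cmt2, 5875 in cmt3a, 1911 in drm2, 2427 in cmt2/cmt3a and 1302 in cmt2/drm2, WT set 2 alone 1394 in cmt2/drm2 and 2009 in cmt3a/drm2, and the mean of both 1165 in drm2 and 1558 in cmt2/cmt3a, since 1 contrast is easier to pass than both.

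For loss of CMT2, CMT3a and DRM2 the 30 libraries as units gave 473, 608 and 2031, as replicates then count as independent. With fewer groups, WT and triple mutant set 1 alone gave 17 for CMT3a and 37 for DRM2, set 2 alone 35 and 115, and fits without the cmt2 and cmt3a lines 20 and 22. With 1 group left out, CMT3a loss called 18 (without cmt2/drm2) to 83 (without triple mutant set 1) and DRM2 loss 64 (without cmt2) to 186 (without WT set 1), against 81 and 217. Of the gene lists 1 of 13 was called with an estimated correlation, 12 after rescaling or with the length trend removed and 10 with a pseudocount of 0.1, where the clock list in cmt2, the defence list in cmt2/drm2 and the phytoalexin list in triple mutant set 1 were lost.

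Without both triple mutant libraries 4 differences in length shares, none of which had passed the test, turned round, to -0.559 for 21 nt by CMT2 loss, -0.224 and -0.216 for 22 nt by CMT2 and CMT3a loss and 0.0141 for 24 nt by CMT2 loss. The stricter filter, with fewer bins, called 461 bins by CMT3a and 2579 by DRM2 loss. Thinned to the smallest library, CMT3a loss called 1047 bins and DRM2 loss 8707. Thinning lowers depth and also evens it between the groups, and which of these moved the counts was not separated. The change of OsCMT2 in cmt2/drm2, which was not called, reversed to 0.10 without cmt2/drm2 replicate 1 and was -0.50 at the lowest, without cmt2/drm2 replicate 3. Except where a construction is named above, the cause was not tested.

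Counts ranged with 1 library left out from 1925 to 2688 in cmt2, 3639 to 4210 in cmt3a, 741 to 768 in drm2, 989 to 1048 in cmt2/cmt3a, 771 to 817 in cmt2/drm2, 1113 to 1176 in cmt3a/drm2, 6158 to 6506 and 5233 to 5357 in the triple mutant sets, 505 to 665 between the WT sets, 1288 to 2041 for cmt2/cmt3a against cmt2, 1167 to 1937 for bins by CMT3a and 10098 to 11173 by DRM2 loss, and the other counts stayed within 1.5 times. Of 2602 values of named genes with 1 left out, 2516 were the same, 83 lost the call and 2 gained it. The replicate numbers share only a number. Deviations of the 135 pairs of libraries with the same number had correlations of -0.226 to 0.443, 10 of them above 0.1, and 9 of 30 libraries correlated best with their own number. With a replicate block the calls were 2307 in cmt2 and 3871 in cmt3a, none of the 287 values of named genes changed its call, and no other count moved past 1.5 times. The alternatives for microRNA levels and for loci without a reference gene, and the count model for bins, were not run, and each alignment is already counted once. The mRNA tables hold no read numbers, so what depth limits among low loci was not measured.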

Other observations

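All tests of this part were chosen after the main results were seen. Other splits of the same libraries into groups of the same sizes were fitted, 100 for each result with the real one included. They asked whether chance in the spread between single libraries can be excluded. It can be excluded, with a share under 0.05, for cmt2 (2307 loci, 3 splits as large, highest other 2737), cmt3a (3870, 4 splits, 4324), drm2 (759, 1 split, 539), cmt2/cmt3a (1007, 1 split, 600), cmt2/drm2 (792, 1 split, 339), cmt3a/drm2 (1169, 2 splits, 1359), triple mutant set 1 (6413, 2 splits, 6982), set 2 (5290, 2 splits, 5917), both sets together (4139, 1 split, 0) and the interaction (7660, 1 split, 5141). In each split as large as the real one the 3 mutant libraries stayed together in a group of their own. The splits move single libraries, so a line or batch difference shared by the 3 libraries of a group is not excluded. Where mutant libraries were mixed, the highest counts were 224 for cmt2, 1004 for cmt3a, 453 for cmt3a/drm2, and 399 and 975 for the triple mutant sets. For the direct comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real values and highest others there were 567 and 1 between the WT sets, 1927 and 3 between the triple mutant sets, 1694 and 0 for cmt2/cmt3a against cmt2, 2989 and 1 against cmt3a, 4778 and 1 for cmt2/drm2 against cmt2, and 6182 and 1 for cmt3a/drm2 against cmt3a.

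For the models of gene loss, few splits called as many loci for CMT3a (81 loci, 2 of 100 splits as large, highest other 1097) and DRM2 (217, 4 of 100 splits, 1749). For CMT2, with 0 loci called by limma, a count of calls cannot test this, and by the 538 loci at an unadjusted p under 0.05 chance cannot be excluded (54 of 100 splits as large, highest other 7071). By that measure it cannot be excluded for CMT3a (1046 loci, 41 of 100 splits, 5907) or DRM2 (3933, 11 of 100 splits, 7259) either. The measures differ, so chance is not excluded for either. Some splits of the 10 groups called several times the real count. Groups that differ by more than the additive losses may be the reason, but this was not tested. For 24 nt bins, chance can be excluded for CMT3a loss (1613 bins, 1 of 100 splits as large, highest other 760) and DRM2 loss (10726, 1 split, 0). The splits do not test depth, and libraries without CMT3a were shallower. For CMT2 loss, with 0 bins called by limma, chance cannot be excluded by the 1483 bins at an unadjusted p under 0.05 (30 of 100 splits, 7113).

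Small RNAs at the loci called in the models of gene loss, in CPM, differed by more than the report gives, each in 5 of 5 libraries (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0476 of 60 tests). Within 2 kb of the loci higher without CMT3a, 21 nt alignments averaged 4.25 ± 2.68 without CMT3a and 0.70 ± 0.129 with it. The triple mutant libraries held 7.03 and 7.23 there, and cmt3a, cmt2/cmt3a and cmt3a/drm2 held 1.94, 1.88 and 3.16. In the loci higher without DRM2 they averaged 4.43 ± 3.04 without DRM2 and 0.482 ± 0.0642 with it, and within 2 kb of them 2.40 ± 0.972 and 0.998 ± 0.197. Within 2 kb of the loci lower without DRM2, 21 nt alignments averaged 1.13 ± 0.218 without DRM2 and 2.06 ± 0.183 with it. In the other tested loci the 21 nt means were 1.14 ± 0.414 and 0.863 ± 0.123 within 2 kb by CMT3a loss, and 1.79 ± 0.919 and 0.744 ± 0.104 inside and 1.13 ± 0.426 and 0.875 ± 0.115 within 2 kb by DRM2 loss, none of which passed (adjusted p = 0.515, 0.0794 and 0.515). In the 5 libraries without the lost gene, 5 loci held 68.3 to 81.1%, 42.6 to 73.8% and 42.3 to 55.9% of these 21 nt alignments at the higher loci, in that order. In the loci higher without CMT3a, 24 nt alignments averaged 11.8 ± 4.56 without DRM2 and 4.26 ± 1.81 with it, but 5 loci held 33.1 to 68.3% of them without DRM2, and the medians overlapped, at 1.60 to 7.17 without it and 0 to 2.78 with it. In the other tested loci 24 nt alignments averaged 3.28 ± 0.330 and 2.45 ± 0.179.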
